A study of Mus musculus with 4 samples.

How the data were processed

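Single-cell 3' RNA libraries had been made from live CD45-positive cells of mouse lung or lung tumor on the 10x Genomics platform, per the labels' protocols. There were 4 libraries, 1 for each pair of genotype (WT or Rab37 KO) and tissue (normal lung or lung tumor), all at day 14. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, over 31053 features. The genome build was mm10, per the submitters' processing notes, and the aligner is not given in the sources used here. The software version is 3.0.1 for both normal libraries and 3.1.0 for both tumor libraries, per the file headers. Every barcode held at least 500 UMIs, so barcodes had been selected before deposit. Gene identifiers were compared with GENCODE vM21, which holds 30934 of them (99.6%).

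Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept, and doublets called by Scrublet in each library were removed. In the order normal WT, normal Rab37 KO, tumor WT, tumor Rab37 KO, 75, 105, 15 and 111 barcodes fell below 200 genes and 314, 268, 14 and 259 lay above 10% mitochondrial UMIs. Scrublet called 227, 110, 3 and 4 doublets (4.33%, 2.33%, 0.46% and 0.15% of cells passing). In all, 13000 of 14396 barcodes remained, with 33822521, 33291597, 5183771 and 30053499 UMIs. Median genes per cell were 1577, 1670, 1401.5 and 1731, and median mitochondrial shares 3.67%, 4.22%, 1.39% and 2.73%. Ribosomal protein genes took 25.0%, 24.2%, 18.5% and 14.3% of UMIs, and the 10 largest genes 10.0%, 10.2%, 13.8% and 15.3%. The tumor WT library had the fewest cells and so the widest intervals.

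All libraries were clustered together without batch correction, from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with seed 1. SPP1 program genes, Rab37 and sex-linked genes were left out of the variable genes. Each cluster took the class whose markers scored highest (mean log2 CPM difference, pseudocount 10 CPM), if the score reached 0.5 and at least 3 markers were found in 10% of its cells. A cluster scoring at least 1 for 2 classes was clustered again (1000 genes, 10 components, resolution 0.5), which turned 28 clusters into 31. Classes carry the ending "-like" because they rest on marker genes alone. The marker lists were fixed beforehand. The score limit went through 3 versions, and the second clustering was added, after clusters had been inspected in output that also showed each cluster's Spp1 level and cells per library.

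Counts were summed over the cells of a class in a library and given as CPM of that sum. Intervals are exact 95% intervals from counting alone: Poisson for CPM, conditional binomial for ratios of 2 libraries and Clopper-Pearson for shares. Where a count was 0, a floor of 3 counts gave the bound of a ratio, and the upper limit of a level was the Poisson one. The share of cells with Spp1 was taken after thinning each cell at random to 1500 UMIs, leaving out cells with fewer. T-like and B-like cells were chosen as background. Cells were called by sex from Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Neutrophil RNA was the share of a cell's UMIs from S100a8, S100a9, Retnlg, Csf3r, Cxcr2, G0s2, Mmp9, Il1r2, Hdc and Mmp8, and its limits of 1% and 0.1% were set after its distribution had been seen.

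Comparisons were Rab37 KO against WT within tumor and within normal lung, and tumor against normal within each genotype. With 1 library per group, cells were not used as replicates and no p-value was computed. Gene lists, the comparisons, the rule for named genes, the filters and 13 alternatives were chosen before the data were examined. The 17 lists were SPP1 macrophage program, osteopontin receptors, alternative activation, inflammatory cytokines, interferon response, antigen presentation, hypoxia and glycolysis, complement and resident macrophage, cytotoxic effector, T cell exhaustion, naive or memory T cell, regulatory T cell, neutrophil granule, tumor neutrophil, Rab and exocytosis machinery, dissociation stress and sex-linked genes. A member counted as measured with at least 10 UMIs over both libraries and as higher or lower at 1.5-fold. A list's median log2 ratio was placed among 10000 random lists of equal size, drawn from 100 genes of similar expression per member, and lists outside their middle 95% were said to lie outside the range.

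Named genes were Rab37, Spp1, Cd44, Itgav, Itgb1 and Itgb3, and by size the 10 genes with the largest ratio each way. The latter needed 200 CPM and 20 UMIs in the higher library and Poisson intervals that did not overlap. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, T cell receptor, sex-linked and predicted genes were left out of that ranking, and 1 ranked gene is not reported here. Up to 4 members of each list with the largest ratio either way and at least 50 CPM in the higher library were also eligible. Genes leading a cluster or serving as its markers are partly set by the naming of classes.

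The interval and list steps were tested on simulated Poisson counts, drawn for each gene independently from the tumor WT and tumor Rab37 KO sums. The intervals assume the same model, so this checks the computation alone. It does not cover UMIs concentrated in few cells or list members that vary together. Over 7954 genes in monocyte/macrophage-like cells, intervals covered 95.6% of unchanged genes and 91.0% of genes changed 2-fold, and excluded 1 for 98.0% of the latter. In T-like cells (2069 genes) these values were 95.8%, 89.0% and 93.0%, and in neutrophil-like cells (2698 genes) 95.8%, 96.0% and 100%. Of 100 lists of unchanged genes, 8, 1 and 3 fell outside the middle 95% in those classes.

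Alternatives chosen beforehand were at least 500 genes, at most 5% mitochondrial UMIs, no doublet removal, resolutions 0.5 and 2.0, and classes given to each cell by its own markers. Under each of these filters and resolutions, clusters were made and named anew, so class membership could change as well. Further ones were median-of-ratios scaling, CPM without mitochondrial and ribosomal genes, the mean of per-cell CPM, a minimum of 1 UMI in each library or of 50 UMIs, thinning to 1000 UMIs and no thinning. After the data were seen, 7 were added: without cluster 8, Scrublet scores above 0.2 removed, macrophage clusters only, cells under 1% neutrophil marker UMIs, clusters weighted alike, cells of 1 sex only, and, for Spp1, without the cell with most Spp1 UMIs in each library (also without the 3 with most). The weighting used the 7 clusters with at least 5 cells in each tumor library. Software was Python 3.11.15, scanpy 1.11.5 (with its Scrublet), anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.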

Results

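Single-cell RNA was counted in live CD45-positive cells sorted from the lungs of C57BL/6 mice, either wild type (WT) or lacking Rab37 (Rab37 KO). Rab37 is a small GTPase of the Rab family, whose members direct vesicle traffic in cells. The mice had received Matrigel without tumor cells (called normal lung here) or LLC cells, a mouse lung carcinoma line, and tissue was taken at day 14. There were 4 groups with 1 library each, so no difference between groups could be set against a spread between replicates, and no test was made. The deposited matrices held 5594 barcodes for normal WT, 5063 for normal Rab37 KO, 674 for tumor WT and 3065 for tumor Rab37 KO, with counts of unique molecular identifiers (UMIs). After filtering, 5015, 4616, 644 and 2725 cells remained in the same order, with median depths of 5032, 5478, 3979 and 6556 UMIs per cell. Intervals are exact 95% intervals for counting error alone, Poisson for levels, conditional binomial for ratios and Clopper-Pearson for shares, and they do not cover variation between animals.

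The labels were first checked against the deleted gene. Rab37 (ENSMUSG00000020732, chromosome 11, 115091431 to 115162236, plus strand, mm10) was counted at 8.52 CPM (interval 7.56 to 9.56) in normal WT and 0.39 (0.21 to 0.67) in normal Rab37 KO. The tumor libraries held 4.63 (2.97 to 6.89) and 0.27 CPM (0.11 to 0.52). The KO/WT ratio was 0.046 (0.024 to 0.080) in normal lung and 0.057 (0.022 to 0.132) in tumor, from 288, 13, 24 and 8 UMIs, which goes with the labels. In WT lung, Rab37 was highest in NK-like cells, at 57.4 CPM in normal lung and 44.0 CPM in tumor, followed by T-like cells at 17.2 and 17.3 CPM. Monocyte/macrophage-like cells of the WT libraries held 15 and 4 Rab37 UMIs, or 3.32 and 1.45 CPM. The deleted part of the gene is not given in the sources used here, and a 3' tag outside it would not check the labels.

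Sex-linked transcripts differed between the libraries and stand beside every tumor comparison of the genotypes. Xist, the RNA made from the inactive X chromosome of female cells, was set against 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty), leaving out 1 cluster (number 27) described with the cell classes. In tumor WT, 408 of 632 cells held Xist and no Y-linked UMI and 0 cells held Y-linked UMIs alone, with 2252 Xist UMIs against 1 Y-linked UMI. In tumor Rab37 KO, 1661 of 2682 cells held Y-linked UMIs alone and 1 held Xist alone, with 4506 Y-linked UMIs against 1 Xist UMI. Cluster 27 of that library, left out here, held 1209 Xist and 2 Y-linked UMIs in 43 cells. The normal libraries held cells of both kinds, 2001 with Xist alone and 1471 with Y-linked UMIs alone in normal WT, and 1533 and 1605 in normal Rab37 KO. Genotype and sex therefore cannot be told apart between the tumor libraries.

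**Figure D1:**
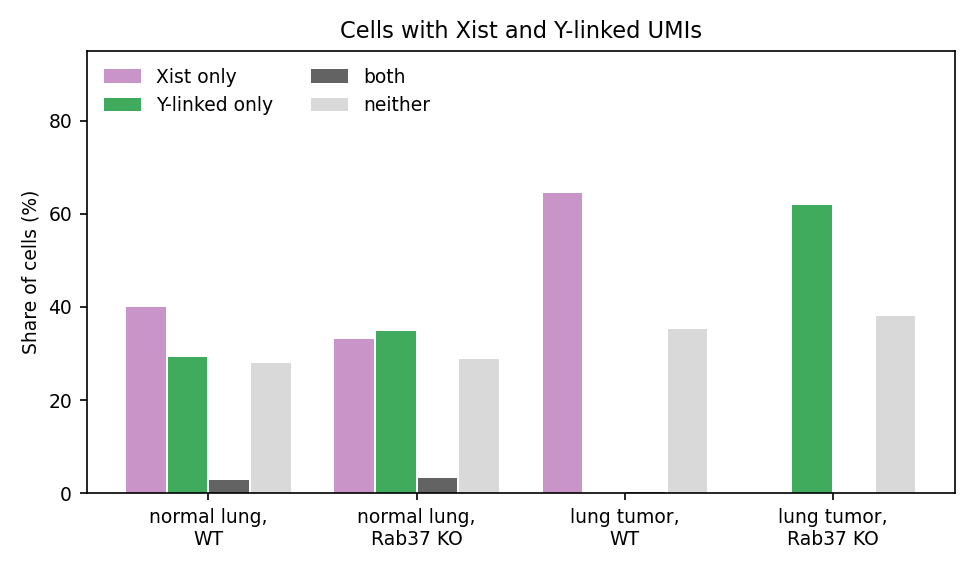
Share of cells (%) in each library with Xist UMIs alone, Y-linked UMIs alone, both or neither, leaving out cluster 27. Xist alone was found in 64.6% of tumor WT cells and Y-linked UMIs alone in 61.9% of tumor Rab37 KO cells, while both normal libraries held cells of both kinds.

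The immune cells of the tumors were mainly neutrophils and monocytes or macrophages, while T cells and alveolar macrophages were the largest classes in normal lung. Neutrophil-like cells made up 32.6% of tumor WT cells (29.0 to 36.4) and 47.1% of tumor Rab37 KO cells (45.2 to 48.9), against 7.66% (6.94 to 8.43) and 12.2% (11.3 to 13.2) in normal lung. Monocyte/macrophage-like cells held 34.3% (30.7 to 38.1) and 31.7% (30.0 to 33.5) in tumor, against 11.5% (10.6 to 12.4) and 10.8% (9.87 to 11.7). T-like cells were 32.7% and 32.5% of normal WT and KO cells, 9.16% of tumor WT cells (7.05 to 11.7) and 2.97% of tumor Rab37 KO cells (2.37 to 3.68). B-like cells had 13.6% and 13.9% in normal lung and 8.54% and 2.35% in tumor. Alveolar macrophage-like cells, the resident phagocytes of the air spaces, held 19.7% and 15.4% in normal lung, 4.04% in tumor WT and 9.17% in tumor Rab37 KO. NK-like cells held 7.54%, 6.48%, 4.19% and 2.28%, and dendritic cell-like cells 4.53%, 3.68%, 4.66% and 2.68%, in the order normal WT, normal KO, tumor WT, tumor KO.

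**Figure D2:**
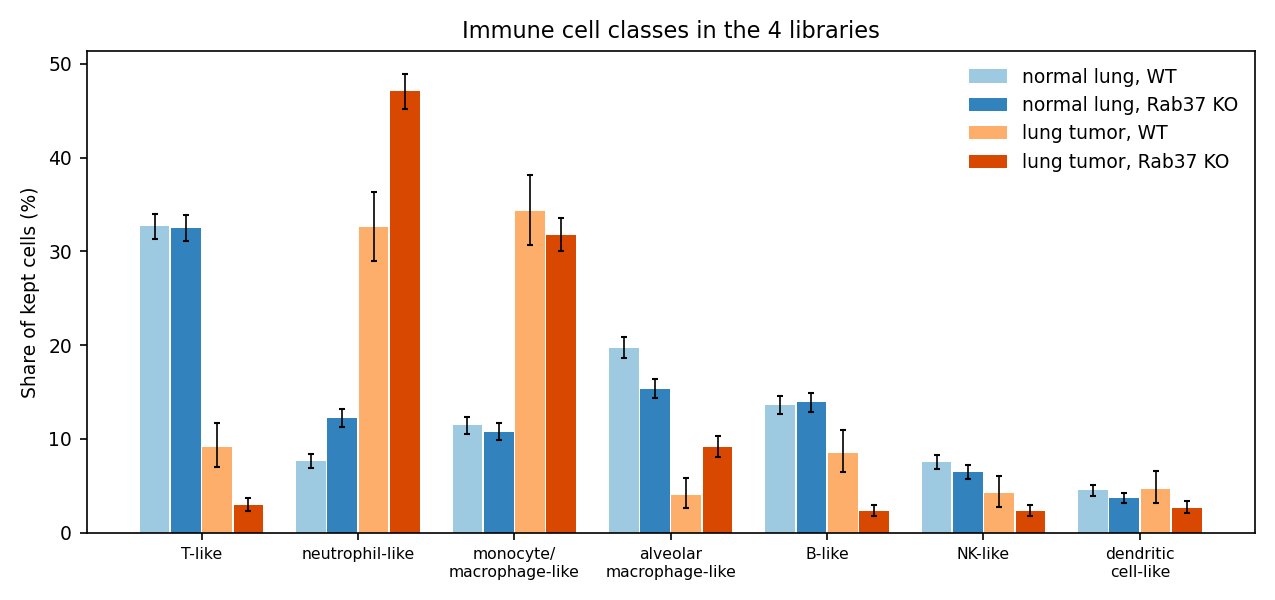
Share of kept cells (%) in the 7 largest named classes by library, with exact 95% binomial intervals as error bars. Neutrophil-like and monocyte/macrophage-like cells lead in both tumor libraries, and T-like cells in both normal libraries.

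ILC2-like, plasma cell-like, fibroblast-like, endothelial-like and epithelial-like cells each made up under 2% of every library. A cluster with 0 cells in the normal libraries, number 27, held 12 tumor WT cells (1.86%) and 43 tumor Rab37 KO cells (1.58%). It was led by Col3a1, Rhox5 and Hmga2 and received no name. The shares describe sorted and captured cells, in barcodes of at least 500 UMIs, so the CD45 gate and cell yield also bear on them. Cluster 8, with 49 and 562 tumor WT and KO cells, entered the monocyte/macrophage-like class through a marker limit set after the clusters were inspected, and without it the class held 26.7% and 11.1% of tumor cells. With classes given to each cell by its own markers, the tumor Rab37 KO share was 20.7%.

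Spp1, the gene of the secreted protein osteopontin (OPN) after which the study's SPP1+ macrophages are named, was lower in monocyte/macrophage-like cells of the Rab37 KO tumor library than of the WT tumor library. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050, plus strand) stood at 7946 CPM (7841 to 8052) in tumor WT and 1668 CPM (1647 to 1690) in tumor Rab37 KO, from 21861 and 23787 UMIs. The KO/WT ratio was 0.210 (0.206 to 0.214), or 4.76-fold lower. It was 0.281 (0.254 to 0.313) in alveolar macrophage-like cells, 0.299 (0.210 to 0.422) in T-like cells, chosen as background although uneven (below), and 0.274 (0.269 to 0.278) over all cells. In dendritic cell-like cells it was 0.452 (0.350 to 0.584), but 2.17 with all cells kept and 2.27 (1.34 to 4.08) without the cell with most Spp1 UMIs in each library. In neutrophil-like cells it was 1.94 (1.75 to 2.16), with 608 CPM in tumor WT and 1180 CPM in tumor Rab37 KO, but 0.858 (0.794 to 0.928) with classes given per cell and 3.096 (2.705 to 3.559) without the largest cell of each library. Few tumor WT cells set the values of the smaller classes: 1 cell held 84.5% of 103 Spp1 UMIs in dendritic cell-like cells and 39.4% of 358 in neutrophil-like cells, and 3 of 26 alveolar macrophage-like cells held 69.2% of 477. Without the largest 3 cells of each library, the alveolar macrophage-like ratio was 0.447 (0.376 to 0.535). In alveolar macrophage-like cells thinned to 1500 UMIs, at least 5 Spp1 UMIs were found in 13.04% (2.78 to 33.6; 3 of 23) in tumor WT and 2.0% (0.65 to 4.61; 5 of 250) in tumor Rab37 KO, and at least 1 in 43.5% (23.2 to 65.5) and 32.0% (26.3 to 38.2). Without thinning, at median depths of 8961 and 11425 UMIs, at least 5 were found in 26.9% (7 of 26) and 27.6% (69 of 250).

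**Figure D3:**
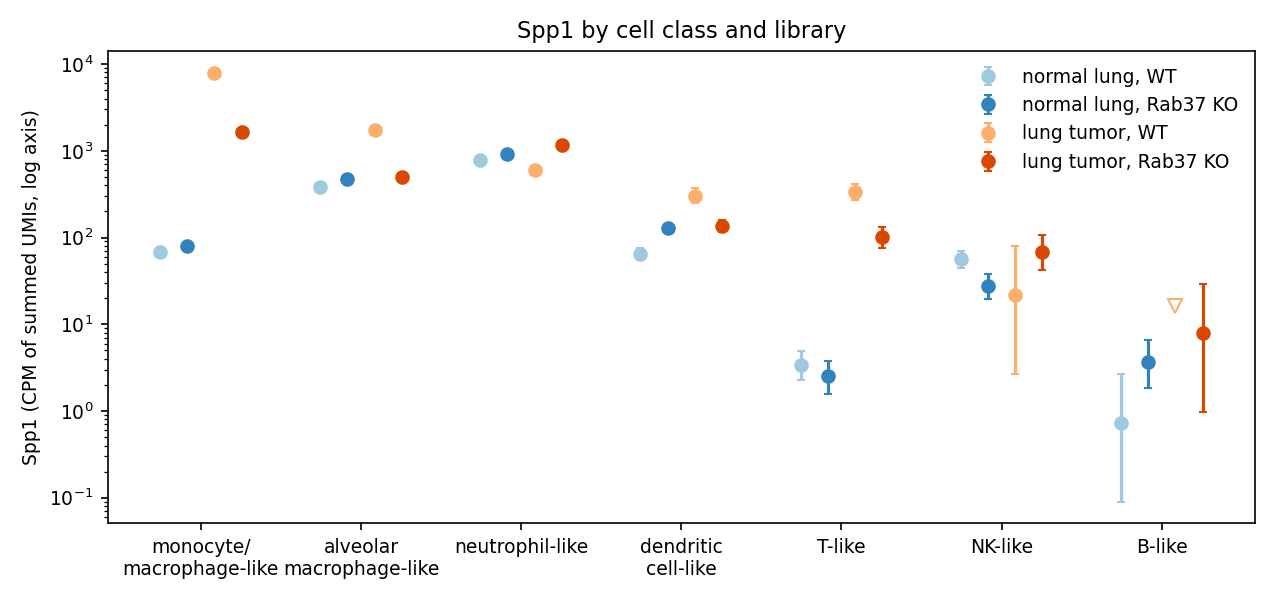
Spp1 in CPM of summed UMIs on a log axis, by cell class and library, with exact 95% Poisson intervals; the open triangle is the upper limit for a count of 0. Monocyte/macrophage-like cells of tumor WT are highest at 7946 CPM, and T-like and B-like cells lie at the bottom in normal lung.

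After each cell was thinned to 1500 UMIs, 54.3% (47.3 to 61.2) of tumor WT monocyte/macrophage-like cells and 47.8% (44.3 to 51.2) of tumor Rab37 KO cells held at least 1 Spp1 UMI. At least 5 were held by 31.7% (25.5 to 38.5; 66 of 208 cells) and 15.2% (12.8 to 17.8; 126 of 829 cells). Thinning left out 13 and 36 shallower cells. As background, T-like cells were chosen, of which 6.90% (4 of 58) in tumor WT and 5.00% (4 of 80) in tumor Rab37 KO held at least 1 Spp1 UMI, and B-like cells, where 0 of 52 and 0 of 64 did. Without thinning, 11 of 59 T-like cells of tumor WT held Spp1 and 6 held at least 5 UMIs, against 0 of 55 B-like cells. In tumor Rab37 KO, 13 and 3 of 81 T-like cells did, and 2 of 64 B-like cells held at least 1. The T-like level in tumor is thus not a background shared by all classes. Median depths were 9512 and 13022 UMIs in the monocyte/macrophage-like cells and 3123 and 5151 in the T-like cells. Without thinning, the monocyte/macrophage-like shares with at least 5 Spp1 UMIs were 54.3% and 48.9%, and at 1000 UMIs the tumor Rab37 KO share was 9.62%.

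Different clusters held most of the class in the tumor libraries. Macrophage clusters 22.0 to 22.2, which carried 10633 Spp1 CPM in tumor WT and 2525 CPM in tumor Rab37 KO, held 58.8% (130 of 221) of the class in tumor WT and 6.2% (54 of 865) in tumor Rab37 KO. Cluster 8, at 3866 and 1696 Spp1 CPM, held 22.2% and 65.0%. It was named classical monocyte with a score of 0.943, and neutrophil-like came second at 0.483. The platelet markers Pf4 and Ppbp were among its leading genes. Within clusters, the KO/WT ratio was 0.256 in 22.0, 0.219 in 22.1, 0.089 in 22.2, 0.439 in cluster 8, 0.641 in cluster 7 and 1.08 (0.975 to 1.20) in macrophage cluster 11, which had 8 tumor WT cells. Nonclassical monocyte clusters 2 and 23 went the other way, with 239.9 CPM (158.1 to 349.0) in Rab37 KO against 0 UMIs in 10 WT cells (upper Poisson limit 127.8) in cluster 2, and 913.6 CPM (816.6 to 1019.1) against 412.3 CPM (133.9 to 962.3; 3 WT cells) in cluster 23. With clusters weighted alike in both libraries, the ratio was 0.316. Spp1 and sex-linked genes were left out of the variable genes. The second clustering, which gave clusters 22.0 to 22.2, was however added after each cluster's Spp1 level had been in view.

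Osteopontin receptor genes did not move as a group. The list's median log2 KO/WT ratio in tumor monocyte/macrophage-like cells was 0.20, at percentile 73.9 of 10000 random lists matched on expression, with 3 of 8 members at least 1.5-fold higher and 1 lower. Cd44, an adhesion receptor, was 2.63-fold higher (2.45 to 2.83; 799 against 303 CPM), and the integrin subunit gene Itgav was 2.15-fold higher (1.74 to 2.69). Itgb5 had a ratio of 0.488 (0.426 to 0.559), Itgb1 0.753 (0.705 to 0.804) and Itgb3 0.884 (0.468 to 1.82). In the macrophage clusters alone, the ratio of Itgb1 was 1.06.

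Beyond Spp1, tumor monocyte/macrophage-like cells of the Rab37 KO library held higher inflammatory cytokine and alternative activation genes and lower antigen presentation genes than those of the WT library. Of 14 measured inflammatory cytokine genes, 12 were at least 1.5-fold higher in Rab37 KO and 1 lower, with a median log2 ratio of 2.18 (percentile 100). Il1b, a cytokine of the interleukin-1 family, was 6.5-fold higher (6.18 to 6.84; 3672 against 565 CPM). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, was 7.13-fold higher, and the chemokine genes Ccl4 and Ccl3 were 7.11-fold and 5.37-fold higher. Of 12 alternative activation genes, 9 were higher and 2 lower (median 1.27, percentile 100). The mannose receptor gene Mrc1, also a macrophage marker here, was 4.34-fold higher, the folate receptor gene Folr2 8.37-fold (5.49 to 13.4) and Ccl24 3.64-fold higher, while Chil3 had a ratio of 0.364. Of 12 antigen presentation genes, 0 were higher and 9 lower (median -1.05, percentile 0.0), among them the MHC class II genes H2-Ab1 and H2-Eb1 with ratios of 0.426 (0.411 to 0.441) and 0.457 (0.439 to 0.475), and the immunoproteasome gene Psmb8 with 0.438.

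The SPP1 macrophage program, which contains Spp1 itself, had 9 of 18 members lower and 3 higher in Rab37 KO (median -0.56, percentile 0.1). Its members Lpl, Gpnmb and Fabp5, of lipid uptake and lysosomal or fatty acid handling, were 7.08-fold, 6.10-fold and 5.78-fold lower. Of 15 hypoxia and glycolysis genes, 8 were higher and 0 lower (median 0.63, percentile 98.8), with Ndrg1 4.97-fold, Egln3 4.08-fold and the glucose transporter gene Slc2a1 4.00-fold higher. The complement and resident macrophage list had a median of -0.28 (percentile 17.6), with Apoe at a ratio of 0.271, Ms4a7 at 0.547 and C1qc at 0.751. The medians of the interferon response (-0.19, percentile 23.9), Rab and exocytosis machinery (0.23, percentile 83.5) and dissociation stress lists (0.46, percentile 95.9) lay within the middle 95% of random lists. Single members still stood apart, such as Bst2 with a ratio of 0.339, the syntaxin gene Stx11, 4.70-fold higher, and the immediate early gene Egr1, 3.93-fold higher.

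**Figure D4:**
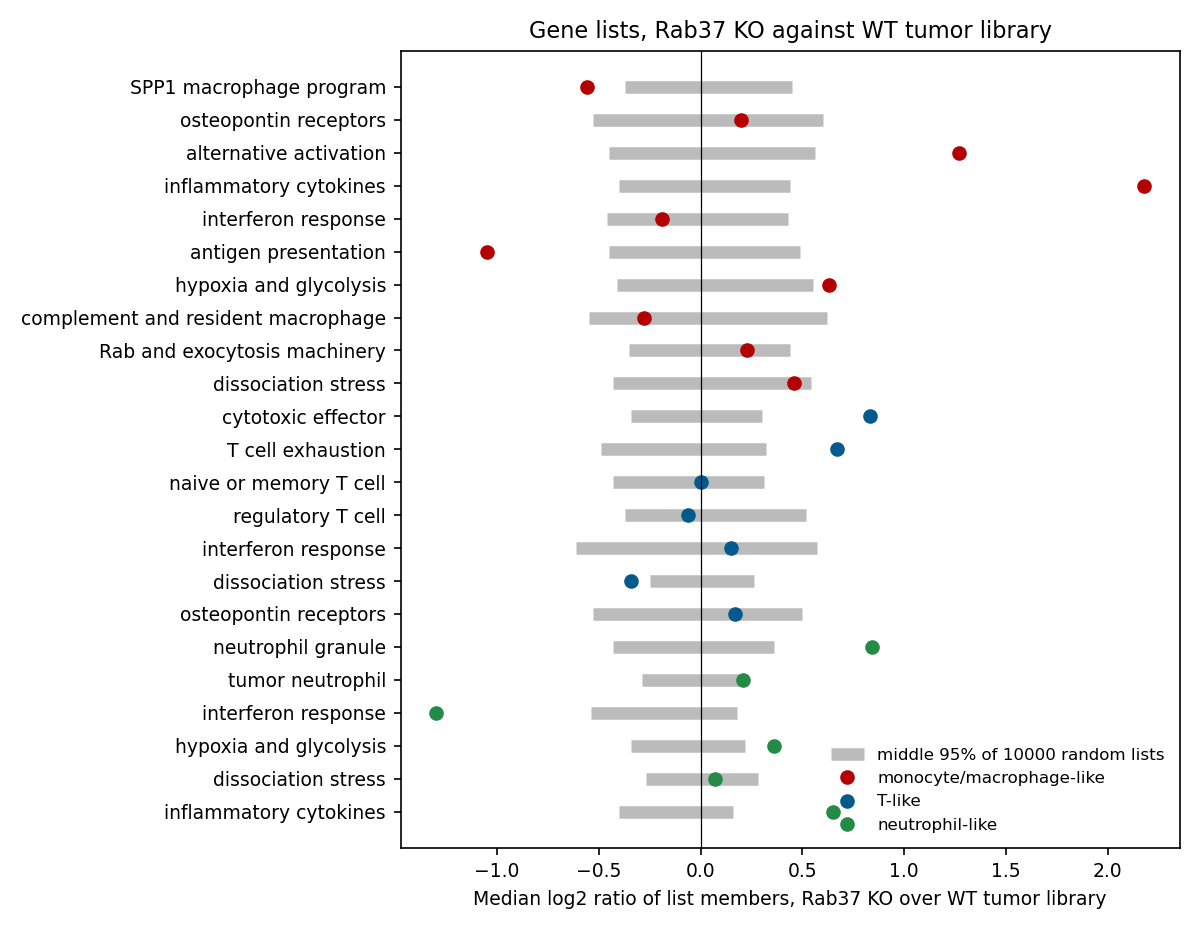
Median log2 KO/WT ratio of each gene list in the tumor libraries (points, by cell class) with the middle 95% of 10000 random lists matched on expression (gray bars). Inflammatory cytokines in monocyte/macrophage-like cells lie highest at 2.18, and the interferon response in neutrophil-like cells lowest at -1.30.

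Neutrophil transcripts in the class also differed between the tumor libraries. Cells with at least 1% of their UMIs from 10 neutrophil markers made up 44.9% (41.5 to 48.2) of the class in tumor Rab37 KO and 13.6% (9.3 to 18.8) in tumor WT, against 17.2% and 19.4% in normal WT and KO and 1.7% and 1.2% of tumor T-like cells. In tumor Rab37 KO, 297 of the 388 such cells of the class lay in cluster 8. They were 52.8% of its 562 cells there, against 20.4% of its 49 cells in tumor WT. Over cells below that limit, 12 of 14 inflammatory genes were still at least 1.5-fold higher (median 1.94). Medians there were 1.82 for alternative activation, -0.91 for antigen presentation, 0.61 for hypoxia and glycolysis and -0.58 for the SPP1 program. Over all cells of the class they were 1.27, -1.05, 0.63 and -0.56. In tumor Rab37 KO, 122 cells lay within 2-fold of the limit. With clusters weighted alike, 9 inflammatory genes were higher (median 0.90) and 8 antigen presentation genes lower (median -0.64), while the SPP1 program (median -0.12), alternative activation (0.22) and hypoxia and glycolysis (0.18) came within the range of random lists. The hypoxia list also did so without cluster 8 (0.34) and in macrophage clusters alone (0.42), where the ratios of Ms4a7 (1.03 and 1.19) and C1qc (1.31 and 1.52) lay above 1.

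Ranked by size, the genes highest in Rab37 KO tumor monocyte/macrophage-like cells had KO/WT ratios of 15.8 for the chemokine gene Cxcl3 (14.3 to 17.4; 2406 against 153 CPM), 12.9 for Stfa2l1, 11.5 for the decoy receptor gene Il1r2, 9.39 for Cxcl1, 9.07 for Ppbp, 6.05 for the histamine-forming enzyme gene Hdc and 5.44 for the metallothionein gene Mt2, besides Ptgs2, Ccl4 and Il1b. Il1r2 and Hdc are neutrophil markers here and Ppbp a platelet marker. Cxcl3, Stfa2l1 and Ccl4 were among the genes leading neutrophil cluster 26, which held 597 tumor Rab37 KO cells. Ccl4, Il1b and Ptgs2 also belong to the tumor neutrophil list. Genes lowest in Rab37 KO were Fabp4 (7.24-fold lower; 6.43 to 8.16), Syngr1 (6.48-fold), the tartrate-resistant acid phosphatase gene Acp5 (6.19-fold), Atp6v0d2 (4.96-fold), Creg1 (4.52-fold) and the cathepsin gene Ctss (4.08-fold), besides Lpl, Gpnmb, Fabp5 and Spp1. Gpnmb, Fabp5, Syngr1 and Spp1 led clusters 22.0 and 22.1, and Ppbp led cluster 8. With clusters weighted alike, the ratio of Atp6v0d2 was 1.07.

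Tumor T-like cells of the Rab37 KO library, 81 against 59 in WT, held higher cytotoxic effector and exhaustion genes. Of 12 cytotoxic genes, 7 were at least 1.5-fold higher and 1 lower (median log2 0.83, percentile 100): the chemokine gene Ccl5 was 4.78-fold higher (4.27 to 5.35), the granule membrane gene Nkg7 3.16-fold (2.47 to 4.08), the death ligand gene Fasl 3.13-fold (1.39 to 8.28) and Gzmk 7.39-fold (1.86 to 64.1; 2 UMIs in WT). The granzyme gene Gzma was the lower member, with a ratio of 0.459 (0.384 to 0.548; 441 against 961 CPM). Of 10 exhaustion genes, 6 were higher and 0 lower (median 0.67, percentile 100), with Nr4a2 at a ratio of 2.81 (1.89 to 4.31), the inhibitory receptor genes Ctla4 at 1.58 (1.21 to 2.09) and Pdcd1 at 1.60 (0.856 to 3.18). Besides Pdcd1, the higher members Entpd1 (0.844 to 7.80) and Cd160 (0.806 to 32.5) had intervals that include 1. Among the higher cytotoxic genes, so did Prf1 (0.913 to 6.80) and Cst7 (0.908 to 4.64). CD8-like cluster 12, led by Ccl5, held 36 of 81 T-like cells in Rab37 KO (44.4%; 33.4 to 55.9) and 13 of 59 in WT (22%; 12.3 to 34.7), and Cd8b1 was 2.54-fold higher. Ccl5, Gzmk and Cd8b1 are CD8 T cell markers here. The dissociation stress list was lower (median -0.34, percentile 0.3), with Hspa1b at 0.419 and Jun at 0.506, but its member Egr1 was 2.48-fold higher (1.64 to 3.88). Naive or memory (0.00), regulatory T cell (-0.06), interferon response (0.15) and osteopontin receptor lists (0.17) lay within the range of random lists. The exhaustion list came within it (median 0.37) when members needed 50 UMIs.

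Few cells set several T-like genes picked by size. Higher in Rab37 KO were Pf4 (52.0-fold; 14.2 to 433), Arg1 (10.3-fold), Thbs1 (8.11-fold), Ly6c2 (7.53-fold), Ccl6 (3.53-fold) and Crem (2.55-fold), but 1 cell held 92.6% of the Pf4, 71.6% of the Arg1 and 53.7% of the Thbs1 UMIs. Lower were Hist1h2ap (9.73-fold), Ifitm1 (9.01-fold), Apoe (7.56-fold), Fabp5 (6.59-fold), Lyz2 (6.46-fold), Wfdc17 (4.98-fold), Paxbp1 (4.29-fold) and Hist1h2ae (3.88-fold). Ctsg and Arhgef40 had 0 UMIs in Rab37 KO and were at least 74.3-fold and 36.5-fold lower against a floor of 3 counts, with 100% and 98.3% of their WT UMIs in 1 cell. In Ifitm1 and Wfdc17, 1 cell held 66.1% and 55.5%, and with classes given per cell their ratios were 4.44 and 1.05. Hist1h2ae UMIs lay in 4 of 59 WT cells, and its ratio was 2.31 at resolution 0.5. Apoe, Lyz2, Fabp5, Thbs1, Pf4 and Arg1 are abundant in myeloid cells or platelets.

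Tumor neutrophil-like cells of the Rab37 KO library held higher granule and cytokine genes and lower interferon response genes than those of the WT library. Of 12 interferon response genes, 0 were higher and 9 lower (median log2 -1.30, percentile 0.0), with the ubiquitin-like modifier gene Isg15 8.31-fold lower (6.70 to 10.3; 31.0 against 258 CPM), Ifit3 7.04-fold and Ifit1 5.13-fold lower. With cells limited to 5% mitochondrial UMIs and clustered anew, that median was -0.30, within the range of random lists. The ratio of Rsad2 was then 1.49 in place of 0.424. Class membership can change under that setting too, so these shifts cannot be laid to cells above 5% alone. Median mitochondrial shares in the class were 0.57% in tumor WT and 1.45% in tumor Rab37 KO. Of 9 granule genes, 6 were higher and 1 lower (median 0.84, percentile 100), including Camp (3.40-fold; 3.03 to 3.81) and Ltf (3.05-fold; 2.62 to 3.58), which encode antimicrobial proteins of the specific granules. Camp UMIs lay in 108 of 1282 cells, and cluster 25, led by Camp, Ngp and Ltf, held 12.3% of the class in Rab37 KO and 9.0% in WT. Of 14 inflammatory genes, 7 were higher and 3 lower (median 0.65, percentile 100), with Il1a 2.81-fold, Ccl2 2.48-fold, Ccl3 2.31-fold and Ccl4 2.29-fold higher. Hypoxia and glycolysis (median 0.36, percentile 99.7; 5 of 15 higher, 0 lower) lay above the range of random lists, and tumor neutrophil (0.21, percentile 96.9) and dissociation stress genes (0.07, percentile 74.9) within it. The median over all genes of this class was -0.24.

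By size, Cxcl1 (2.91-fold), Hspa1b (2.62-fold), Cxcl3 (2.58-fold), Slc9a3r1 (2.42-fold) and Ccl6 (2.29-fold) were also among the highest in Rab37 KO neutrophil-like cells. Creg1 (2.86-fold), Tmsb10 (2.81-fold), Apoe (2.68-fold), Csf1 (2.54-fold), Ifi27l2a (2.18-fold), Psap (2.16-fold), Cd74 (2.01-fold) and Atp5j (1.97-fold) were lower. For Cd74, 41.8% of the WT UMIs came from 1 cell. Alveolar macrophage-like cells, 26 in tumor WT and 250 in tumor Rab37 KO, had median log2 KO/WT ratios of -0.82 for the SPP1 program (11 of 18 lower, 0 higher), -0.71 for interferon response, -0.65 for antigen presentation, -0.47 for hypoxia and glycolysis and 0.46 for inflammatory cytokines, each outside the range of random lists. Few cells weighed on the WT side of these values: the 3 cells with most held 39.3% of the SPP1 program UMIs, 44.4% of the interferon, 39.5% of the antigen presentation, 41% of the hypoxia and glycolysis and 46.6% of the inflammatory UMIs. For the program members Arg1 and Mmp12, 3 cells held 99.6% and 97.1% of the WT UMIs.

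In normal lung, the genotypes differed less in Spp1. Monocyte/macrophage-like cells held 68.8 CPM (61.4 to 76.9) in WT and 79.8 CPM (71.5 to 88.9) in Rab37 KO, a ratio of 1.16 with an interval (0.991 to 1.36) that includes 1. This ratio depended on which cells were used: it was 0.464 (0.313 to 0.678) over cells with Xist alone, 1.91 (1.40 to 2.62) over cells with Y-linked UMIs alone and 0.570 over cells with under 1% neutrophil marker UMIs. The ratios by sex rest on 40 against 96 and 127 against 64 UMIs. In the whole class, 3 cells held 43.2% of 333 UMIs in Rab37 KO and 29.6% of 311 in WT. Without the largest 3 cells of each library the ratio was 0.942 (0.771 to 1.15). Over all cells it was 1.20 (1.16 to 1.24), in alveolar macrophage-like cells 1.26 (1.21 to 1.32), in neutrophil-like cells 1.16 (1.06 to 1.27; 0.818 over cells with Xist alone and 2.44 over cells with Y-linked UMIs alone) and in dendritic cell-like cells 1.97 (1.61 to 2.40), where 1 cell held 49.6% of the Rab37 KO UMIs and the ratio was 1.37 (1.06 to 1.77) without the largest cell and 1.08 (0.792 to 1.47) without the largest 3 cells of each library. At least 1 Spp1 UMI in 1500 was found in 5.24% and 4.03% of monocyte/macrophage-like cells of normal WT and KO, against 0.31% and 0.13% of T-like cells. Cd44 had a ratio of 1.17, Itgav 1.01, Itgb1 0.912 and Itgb3 1.20.

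Normal-lung gene lists in monocyte/macrophage-like cells mostly lay near 0, with 15 of 18 SPP1 program genes within 1.5-fold (median log2 0.01, percentile 33.0). Alternative activation was higher in Rab37 KO (median 0.42, percentile 100; 3 of 13 higher, 1 lower), with the scavenger receptor genes Cd163 at a ratio of 1.93 (1.58 to 2.36) and Stab1 at 1.72 (1.49 to 1.98). Complement and resident macrophage genes (0.21, percentile 99.2), osteopontin receptors (0.25, percentile 98.9) and dissociation stress genes (0.09, percentile 98.6) lay above the range of random lists, with at most 1 member of each past 1.5-fold. With cells limited to 5% mitochondrial UMIs and clustered anew, alternative activation stood at -0.03 and complement genes at -0.11. Over cells with Y-linked UMIs alone, receptors stood at -0.14 and stress genes at -0.03. Inflammatory cytokines (0.07), interferon response (-0.03), antigen presentation (-0.01), hypoxia and glycolysis (0.03) and Rab and exocytosis machinery (-0.08) lay within the range, while the SPP1 program lay below it in macrophage clusters alone (-0.21). In alveolar macrophage-like cells, inflammatory cytokines were lower in Rab37 KO (median -0.78, percentile 0.0; 7 of 13 lower, 1 higher), with a median of -1.43 over cells with Xist alone and -0.02 over cells with Y-linked UMIs alone.

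Normal-lung neutrophil-like cells of the Rab37 KO library held higher granule genes, with 6 of 8 at least 1.5-fold higher and 0 lower (median log2 1.25, percentile 100). Ltf was 6.14-fold higher (4.71 to 8.14), Camp 5.32-fold (4.65 to 6.11) and Ngp 2.69-fold higher (2.44 to 2.96). Cluster 25, led by Camp, Ngp and Ltf, held 7 of 565 cells of the class in Rab37 KO (1.2%) and 4 of 384 in WT (1.0%). Few cells may therefore carry these values. Interferon response genes had a median of 0.33 (percentile 98.1), which was -0.56 with cells limited to 5% mitochondrial UMIs and clustered anew. Stress genes had -0.23 (percentile 0.1). T-like cells had medians of 0.06 for cytotoxic, 0.12 for exhaustion, -0.07 for naive or memory and -0.02 for regulatory T cell genes, within the range of random lists, and -0.14 (percentile 0.0) for dissociation stress.

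Tumor and normal libraries were compared within each genotype, bearing in mind that the matrix headers name software version 3.0.1 for both normal and 3.1.0 for both tumor libraries. Spp1 in monocyte/macrophage-like cells was 116-fold higher in tumor than in normal WT lung (103 to 130) and 20.9-fold higher in Rab37 KO (18.8 to 23.4). These ratios ranged from 75.7 with each cell given the same weight to 189 over cells under 1% neutrophil marker UMIs in WT, and reached 70.3 over the latter cells and 31.8 in macrophage clusters alone in Rab37 KO. Within cells of the same sex they were 133 in WT (Xist alone) and 17.6 in Rab37 KO (Y-linked UMIs alone). Spp1 in alveolar macrophage-like cells was 4.64-fold higher (4.21 to 5.10) in WT tumor, with a ratio of 1.03 (0.975 to 1.10) in Rab37 KO, and within cells of the same sex these ratios were 4.94 (4.46 to 5.47) and 0.782 (0.726 to 0.842). Without the largest 3 cells of each library they were 2.02 (1.70 to 2.38) and 0.709 (0.661 to 0.760). At least 5 Spp1 UMIs in 1500 were found in 1.42% (0.78 to 2.38; 14 of 984) of these cells in normal WT and, as given above, in 3 of 23 in tumor WT. In neutrophil-like cells the ratio was 0.768 (0.675 to 0.872) in WT, but 1.77 with classes given per cell, and 1.28 (1.21 to 1.36) in Rab37 KO. Within neutrophil-like cells of the same sex both ratios lay below 1, at 0.206 (0.144 to 0.294; 50 tumor and 14 normal cells) in WT and 0.727 (0.677 to 0.781; 607 and 193 cells) in Rab37 KO. T-like cells, chosen as background, went from 3.38 to 335 CPM in WT and from 2.51 to 100 CPM in Rab37 KO. Without thinning, 11 of 59 T-like and 0 of 55 B-like cells of tumor WT held Spp1, so 335 CPM is not a background shared by all classes.

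The SPP1 macrophage program and glycolytic genes were higher in tumor in both genotypes. Of 18 program genes, 17 were at least 1.5-fold higher in WT (median log2 3.06, percentile 100) and 15 in Rab37 KO (2.65, percentile 100). In WT, the arginase gene Arg1 was 336-fold higher (196 to 632), Gpnmb 68.7-fold, Fabp5 36.4-fold, the macrophage elastase gene Mmp12 20.8-fold, the lipid receptor gene Trem2 9.99-fold, and the lysosomal genes Ctsl, Cd63 and Ctsd 9.42-fold, 7.34-fold and 7.32-fold higher. Syngr1 was 464-fold higher (128 to 3842), from 2 UMIs in normal WT. Hypoxia and glycolysis genes were higher for 14 of 15 members in WT (median 1.60) and 15 of 15 in Rab37 KO (2.41), with Bnip3 11.6-fold and 21-fold higher and Tpi1 5.18-fold and 7.84-fold. Antigen presentation genes were lower in Rab37 KO tumor (median -0.91, percentile 0.0; 10 of 12 lower, 0 higher) and within the range of random lists in WT (-0.10). Clusters 2, 11, 7 and 23 held 36.8%, 21.1%, 20.9% and 16.4% of the class in normal WT, and clusters 22.0 to 22.2 and 8 held 58.8% and 22.2% in tumor WT.

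Inflammatory cytokine genes went opposite ways in the 2 genotypes. They were lower in WT tumor (median -1.0, percentile 0.0; 10 of 14 lower, 2 higher) and higher in Rab37 KO tumor (0.84, percentile 100; 10 of 15 higher, 3 lower), although the latter was 0.07 without cluster 8 and -0.21 in macrophage clusters alone, both within the range of random lists. Neutrophil transcripts moved with the Rab37 KO value: 44.9% of the class in tumor and 19.4% in normal lung held at least 1% neutrophil marker UMIs, and over cells below that limit the median was 0.57 (percentile 99.8). Ccl4 had a ratio of 0.242 in WT and Tnf 0.292, while in Rab37 KO Cxcl2 was 3.25-fold and Il1b 2.43-fold higher. Dissociation stress genes were lower in tumor in both genotypes (medians -0.96 and -0.65), with the heat shock gene Hspa1b 10.6-fold lower in WT and 9.07-fold lower in Rab37 KO. Osteopontin receptors were lower in WT (-0.93, percentile 0.2; Cd44 ratio 0.417, Itgav 0.516) and near 0 in Rab37 KO (0.02). Other genes lower in WT tumor by size were Cd83 (15.6-fold), Ace (13.4-fold), Cxcl10 (8.54-fold), Stap1 (7.89-fold), Nr4a1 (7.60-fold), Scgb1a1 (15.5-fold), Retnla (11.5-fold), Cxcl13 (617-fold; 110.5 to 24397, from 1 UMI in tumor) and Prg4 (at least 229-fold, 0 UMIs in tumor). Ace and Nr4a1 are nonclassical monocyte markers here, and 1 cell held 82.1% of the Scgb1a1 and 58.6% of the Retnla UMIs. Alternative activation (-0.29 and 0.14), interferon response (-0.09 and -0.03) and complement genes (0.39 and -0.08) lay within the range in both genotypes, and Rab and exocytosis genes in WT (-0.12) but above it in Rab37 KO (0.32, percentile 98.5).

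T-like cells of both tumors held higher regulatory and exhaustion genes and lower naive or memory genes than those of normal lung. Regulatory T cell genes were at least 1.5-fold higher for 8 of 8 members in WT (median log2 1.99) and in Rab37 KO (2.02), with the lineage factor gene Foxp3 7.09-fold (4.24 to 11.4) and 6.12-fold (4.07 to 9.03) higher. Exhaustion genes had medians of 1.42 and 1.87, with Tnfrsf9 15.4-fold and 13.4-fold higher. Naive or memory genes had medians of -0.75 and -0.84, with the lymph node homing receptor gene Ccr7 4.58-fold and 4.18-fold lower. Cytotoxic genes had medians of 0.55 (percentile 89.2) in WT and 1.32 (percentile 100) in Rab37 KO. The median over all genes was 0.50 in WT and 0.28 in Rab37 KO. CD4-like cluster 1, led by Tnfrsf4, Ctla4 and Ikzf2, held 42.4% of tumor WT and 27.2% of tumor KO T-like cells, against 15.9% and 12.4% in normal lung.

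Tumor neutrophil-like cells held higher granule genes (medians 1.19 in WT and 0.87 in Rab37 KO) and hypoxia and glycolysis genes (1.07 and 1.37) than those of normal lung. The tumor neutrophil list lay within the range of random lists (medians -0.40, percentile 12.7, and 0.22, percentile 94.6), with 3 of 14 members higher and 4 lower in WT and 4 higher and 3 lower in Rab37 KO. Among them, Wfdc17 was 20.2-fold and 12.9-fold higher, while Trem1 had ratios of 0.529 and 0.492 and Ptgs2 0.395 and 0.645. Interferon response genes were higher in WT tumor (1.32, percentile 99.9; 9 of 12 higher, 0 lower) and lower in Rab37 KO tumor (-0.69, percentile 0.0; 6 of 12 lower, 2 higher), with Isg15 at ratios of 2.51 (1.93 to 3.27) and 0.225 (0.185 to 0.273). With cells limited to 5% mitochondrial UMIs and clustered anew, the medians were 0.38 in WT, within the range of random lists, and 0.94 in Rab37 KO. Cluster 9 held 96.4% and 98.1% of neutrophil-like cells in normal lung, and clusters 17, 25 and 26 held most in tumor. Alveolar macrophage-like cells of WT tumor had medians of 1.93 for the SPP1 program, 0.91 for antigen presentation and -1.29 for inflammatory cytokines, and those of Rab37 KO tumor 0.12, 0.40 and -0.47. The WT values rest on the same 26 tumor cells. Over cells of the same sex, the program had 1.99 in WT and 0.13 (percentile 96.1) in Rab37 KO, and inflammatory cytokines -1.88 in WT and -0.09 (percentile 13.8) in Rab37 KO. Both of these Rab37 KO values lay within the range of random lists.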

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

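In this part, the tests on cluster weighting of Spp1, on Spp1 in other cell types, on Spp1 by sex, on leaving out the cells with most Spp1, on cells under 0.1% neutrophil marker UMIs and on Y-linked UMIs in cluster 27 were chosen only after the result was seen. The other tests were chosen once the patterns had been seen, but before their own values. The differences below were flagged because 2 groups moved in opposite directions or because a signal lay outside the comparisons. None of these differences was tested, since each group had 1 library.

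Spp1 KO/WT ratios lay below 1 in tumor and above 1 in normal lung over all cells (0.274 and 1.20), in alveolar macrophage-like cells (0.281 and 1.26) and in dendritic cell-like cells (0.452 and 1.97). In tumor WT, 1 dendritic cell-like cell held 84.5% of the Spp1 UMIs and 3 of 26 alveolar macrophage-like cells held 69.2%, and in normal lung 1 Rab37 KO dendritic cell-like cell held 49.6%. Without the largest cell of each library the dendritic cell-like ratios were 2.27 in tumor and 1.37 in normal lung, both above 1, and without the largest 3 cells the alveolar ones were 0.447 and 1.27. Interferon response genes of neutrophil-like cells had a median log2 KO/WT ratio of -1.30 in tumor and 0.33 in normal lung. With at most 5% mitochondrial UMIs and clusters made anew, these were -0.30 and -0.56. Inflammatory cytokine genes of alveolar macrophage-like cells had 0.46 in tumor and -0.78 in normal lung, but -0.02 over male cells of normal lung. Between tumor and normal lung, the Spp1 ratio in neutrophil-like cells was 0.768 in WT and 1.28 in Rab37 KO, but 0.206 over female WT cells and 0.727 over male Rab37 KO cells, both below 1. Inflammatory genes of monocyte/macrophage-like cells had tumor over normal medians of -1.0 in WT and 0.84 in Rab37 KO, but -0.21 in Rab37 KO with macrophage clusters only. Interferon genes of neutrophil-like cells had 1.32 and -0.69, but 0.38 and 0.94 with at most 5% mitochondrial UMIs and clusters made anew. In normal lung, the Spp1 KO/WT ratio in monocyte/macrophage-like cells was 0.464 over female cells and 1.91 over male cells, and the inflammatory median was -0.73 and 0.33. These Spp1 ratios rest on 40 against 96 and 127 against 64 UMIs, and 3 cells held 43.2% of the class's Spp1 UMIs in normal Rab37 KO. Cluster 27, with no cells in normal lung, held 1.86% of tumor WT and 1.58% of tumor Rab37 KO cells.

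The first pattern weighed was lower Spp1 in monocyte/macrophage-like cells of the Rab37 KO tumor library. With clusters weighted alike the KO/WT ratio was 0.316, against 0.210 unweighted, so the mix of clusters may account for part of the difference but not all of it. Over cells with under 1% neutrophil marker UMIs the ratio was 0.212 (0.207 to 0.217), which leaves neutrophil RNA out as the cause. A drop as large as in this class was not found in neutrophil-like cells. Whether a smaller drop was shared by every cell type stays open. The ratio was 0.281 in alveolar macrophage-like cells, or 0.447 without the largest 3 cells of each library, and 0.299 in T-like cells, where 11 of 59 tumor WT cells held Spp1. In neutrophil-like cells it was 1.94, or 0.858 with classes given per cell, and in dendritic cell-like cells 0.452, or 2.27 without the largest cell of each library. Within the class, the ratio was 1.08 in cluster 11, and Spp1 stood higher in Rab37 KO in cluster 2. In cluster 23 the intervals overlapped, at 816.6 to 1019.1 CPM in Rab37 KO and 133.9 to 962.3 CPM in WT. These clusters had 8, 10 and 3 tumor WT cells. Sex cannot be set apart from genotype: the male/female Spp1 ratio was 0.806 (0.578 to 1.12; 64 against 96 UMIs) in normal WT and 3.31 (2.31 to 4.86; 127 against 40 UMIs) in normal Rab37 KO. Both loss of Rab37 and differences between the animals therefore remain possible.

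The second pattern was higher inflammatory cytokine genes in the same cells. Of 14 genes, 12 stayed at least 1.5-fold higher over cells with under 1% neutrophil marker UMIs, and 9 stayed so with clusters weighted alike, so neither explains the whole pattern. Doublets with neutrophils do not explain the whole pattern either, since 12 of 14 genes stayed higher (median log2 2.03) over 318 Rab37 KO and 163 WT cells with under 0.1% neutrophil marker UMIs. Whether they add to it stays open: in normal lung, 30.0% (23.2 to 37.5) of sex-called cells of the class with at least 1% neutrophil marker UMIs held both Xist and Y-linked UMIs, against 13.6% (11 to 16.4) below that limit. In T-like cells of these libraries the share was 1.0% (0.7 to 1.5) and in neutrophil-like cells 2.4% (1.0 to 4.6). Median depths were 7601, 6504, 5063 and 2418 UMIs in the same order. Doublets may thus also lie among cells of the class below the limit. Sex could not be ruled out, with median male/female log2 ratios of -0.25 in normal WT and 0.36 in normal Rab37 KO.

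The third pattern was cluster 27. In the Rab37 KO tumor library 4.7% (0.6 to 15.8) of its cells held a Y-linked UMI, against 61.9% of the other cells, which speaks against host immune cells. Xist, looked at afterwards, goes the same way: 33 of its 43 cells in that library held it (76.7%), against 1 of 2682 other cells. Ptprc, the gene of CD45, stood at 0.012 times the level of the other cells in that library and 0.003 times in tumor WT. Implanted tumor cells that passed the gate would give such values, and this remains a hypothesis, because no reference profile of LLC cells was compared.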

How the results depend on the processing

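In this part, the settings without cluster 8, with macrophage clusters only, with cells under 1% neutrophil marker UMIs, with clusters weighted alike, with cells of 1 sex and without the largest Spp1 cell were chosen only after the data were seen. No paired analysis was possible because each group has 1 library. Among the main results, 267 values under planned settings stayed the same, 32 moved past the counting interval and 2 lost their place outside the range of random lists; under added settings 77 stayed, 24 moved, 5 lost and 1 gained it. Among other values, 18 under planned and 19 under added settings turned direction. The KO/WT ratio of Rab37 ranged from 0.042 to 0.050 in normal lung and from 0.033 to 0.066 in tumor. The tumor KO/WT ratio of Spp1 in monocyte/macrophage-like cells stayed below 1 throughout, from 0.186 to 0.316, while in normal lung it ran from 0.464 to 1.91. The tumor WT library, with 644 cells, limits every tumor comparison, and T-like values rest on 59 and 81 cells. The class limits were set in view of each cluster's Spp1 level, as processing states. The cause was not tested for any value below.

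Values of Spp1 and of the shares are for monocyte/macrophage-like cells unless stated. With at least 500 genes the tumor KO/WT ratio of Spp1 was 0.221. With at most 5% mitochondrial UMIs it was 0.216. Neutrophil-like cells then had a tumor KO/WT ratio of Rsad2 of 1.493, and interferon medians of -0.30 (KO/WT tumor), -0.56 (KO/WT normal) and 0.94 (tumor/normal in KO). In normal lung C1qa had 0.998, alternative activation -0.03 and complement genes -0.11. Shares were 26.23% T-like in normal KO, 8.80%, 17.13% and 50.87% neutrophil-like in normal WT, normal KO and tumor KO, and 12.52% and 29.11% monocyte/macrophage-like in normal and tumor KO.

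With all cells kept, Spp1 had 0.218 (KO/WT tumor), 1.359 (KO/WT normal) and 18.703 (tumor/normal in KO), and in dendritic cell-like cells 2.166 (KO/WT tumor) and 0.618 (tumor/normal in WT). At resolution 0.5 the T-like ratio of Hist1h2ae was 2.307. At resolution 2.0 Spp1 had 0.223 in tumor and the tumor KO share was 29.87%. With classes per cell, Spp1 had 0.217 (KO/WT tumor), 0.964 (normal) and 24.308 (tumor/normal in KO), and in neutrophil-like cells 0.858 (KO/WT tumor) and 1.766 (tumor/normal in WT). T-like Ifitm1, Wfdc17 and Satb1 had 4.437, 1.045 and 0.958, Bst2 (tumor/normal in KO) 1.098, and inflammatory genes in alveolar macrophage-like cells (tumor/normal in KO) 0.02. Shares were 27.80% neutrophil-like in tumor WT and 9.97%, 9.19% and 20.66% in normal WT, normal KO and tumor KO.

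Without cluster 8, Spp1 had 0.186 (KO/WT tumor), 1.413 (normal) and 151.91 (tumor/normal in WT). Tumor KO/WT values were 1.028 for Ms4a7, 1.307 for C1qc and 0.34 for hypoxia genes, and Bst2 (tumor/normal in KO) had 1.480. Shares were 26.71% and 11.12% in tumor WT and KO, with at least 1 Spp1 UMI in 39.07% of tumor KO cells. With macrophage clusters only, Spp1 had 0.203 (KO/WT tumor), 165.109 and 31.761 (tumor/normal in WT and KO). Tumor KO/WT values were 1.190 for Ms4a7, 1.522 for C1qc, 1.057 for Itgb1 and 0.42 for hypoxia genes. In normal lung, Vegfa had 1.330 and the SPP1 program -0.21. Tumor/normal ratios in WT were 0.614 for Ccl24, 0.923 for H2-DMb1, 0.787 for C3ar1, 0.727 for C1qb and 1.436 for Irf7. In KO they were 1.571 for Bst2, with an inflammatory median of -0.21. At least 1 Spp1 UMI was held by 69.77% and 56.58% and at least 5 by 41.86% and 23.03% of tumor WT and KO cells.

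With cells under 1% neutrophil marker UMIs, Spp1 had 0.570 (KO/WT normal), 189.369 and 70.298 (tumor/normal in WT and KO), Snap23 (tumor/normal in WT) 1.027, and 41.43% of tumor KO cells held at least 1 Spp1 UMI. After thinning to 1000 UMIs, 42.16% of tumor KO cells held at least 1 and 9.62% at least 5. Without thinning, 69.23% and 54.30% of tumor WT and 68.79% and 48.90% of tumor KO cells did. Median-of-ratios scaling gave Spp1 0.221 (KO/WT tumor) and 23.520 (tumor/normal in KO). The mean of per-cell CPM gave 0.264 (KO/WT tumor), 0.785 (normal), 75.713 and 25.415 (tumor/normal in WT and KO), and in KO Ms4a7 0.998 and Folr2 0.915. With at least 50 UMIs per member the T-like exhaustion median was 0.37. With clusters weighted alike, tumor KO/WT values were 0.316 for Spp1, 1.068 for Atp6v0d2, -0.12 for the SPP1 program, 0.22 for alternative activation and 0.18 for hypoxia genes. Female cells gave Spp1 0.464 (KO/WT normal) and 132.917 (tumor/normal in WT). Male cells gave 1.908 and 17.633 (tumor/normal in KO), with normal KO/WT medians of -0.14 for receptors and -0.03 for stress genes. Without the largest Spp1 cell of each library, Spp1 had 0.215 (KO/WT tumor) and 25.088 (tumor/normal in KO), and in dendritic cell-like cells 2.265 (KO/WT tumor).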

Other observations

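Alveolar macrophage-like cells high in cytokine genes came mostly from female cells of the normal WT library. Cluster 16, led by Cxcl10, Tnf and Il1a, held 67 of 460 female alveolar macrophage-like cells of normal WT (14.6%; 11.5 to 18.1) and 2 of 416 male cells (0.5%; 0.1 to 1.7), besides 6 of 36 cells with both Xist and Y-linked UMIs (16.7%; 6.4 to 32.8). In normal Rab37 KO it held 1 of 258 female cells (0.4%; 0.0 to 2.1) and 7 of 348 male cells (2.0%; 0.8 to 4.1). The median log2 male/female ratio of the inflammatory list in these cells was -1.38 in normal WT and 0.23 in normal Rab37 KO.

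Spp1 in neutrophil-like cells of normal lung also differed by sex call. The KO/WT ratio was 2.44 (2.06 to 2.92; 1601 against 656 CPM) over 193 and 93 male cells and 0.818 (0.608 to 1.11) over 29 and 14 female cells. Cluster 27 of the tumor libraries held 12.0% of tumor WT and 11.9% of tumor Rab37 KO UMIs, with median depths of 43012 and 81121 UMIs per cell. It held Col3a1 at 1914 and 1435 CPM, Rhox5 at 774 and 712 CPM, Hmga2 at 377 and 389 CPM, the proliferation marker Mki67 at 267 and 182 CPM, and Spp1 at 2057 and 1328 CPM. These groups were singled out after their values were seen.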
